A study of Mus musculus with 5 samples.

How the data were processed

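Total RNA was taken from PDPN-positive, CD45-negative, EpCAM-negative, E-cadherin-negative cells sorted from KPC mouse pancreatic tumours, per the labels' protocols. Libraries were made with a directional kit after depletion of ribosomal RNA and sequenced in paired ends on a NovaSeq instrument. Samples were grouped by their treatment label into vehicle (n = 3) and LDE225 (n = 2). The labels do not say whether each library came from its own mouse, so the p-values measure the spread between these samples, which may be technical.

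The deposited values are a signal per gene, namely DESeq2-normalised read counts that are neither log-transformed nor scaled for gene length, for 15180 genes all typed as protein-coding. STAR 2.7.3, RSEM 1.2.29, DESeq2 1.22.2 and the build GRCm38 are named per the submitters' processing notes, without role, order or parameters. The annotation release, the filter on genes and the strand setting of the counting are not given in the sources used here. Every gene kept in the deposited table had at least 6 recovered reads over the 5 libraries. Of the gene symbols, 23 had been turned into dates by a spreadsheet and were restored from their Ensembl identifiers. A further 33 entries shared 15 symbols and were kept apart by identifier. Another 3 columns without a header held leftover entries for 9 genes and were not used.

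Each value was a whole multiple of the smallest positive value of its library, within 0.001 reads, for 100% of values, which gave whole reads: 7578822, 11194991 and 9319936 for vehicle 1, 2 and 3, and 13671817 and 14083280.0 for LDE225 1 and 2. These are reads on the deposited protein-coding genes, not the full library. No pair of libraries agreed within sampling noise (chi-square per degree of freedom between 24.4 and 134), so all 5 were counted as separate samples. This check compares with counting noise alone and cannot tell whether any libraries came from the same mouse. Size-factor normalisation removes a shared difference in depth but not a difference in composition, and deeper libraries can detect more low genes. Between 14264 and 14829 genes had a read. This did not follow depth throughout, since vehicle 3 had 14774 such genes and the deeper vehicle 2 had 14591.

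The main test was limma 3.58.1 in R 4.3.3 (empirical Bayes with a mean trend) on log2(value + 1), for 13183 genes with a mean of at least 10, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Fold changes are on that log2(value + 1) scale, which understates changes of low genes. The test was fixed before the data were examined, from labels that named DESeq2-normalised values. An exact rank test of a single value over the 10 arrangements of the libraries cannot go below p = 0.2 two-sided, so none was used for genes. Counts were simulated for the same 13183 genes, with 50 genes changed at each size. On these limma called 16% of 2-fold, 84% of 4-fold, 78% of 8-fold and 94% of 16-fold changes and 11 unchanged genes. In edgeR the shares were 20%, 84%, 78% and 92% with 14 unchanged genes, and in DESeq2 40%, 90%, 82% and 98% with 52. Each gene was simulated independently, without variation shared by genes within a library, so these shares may not hold for the real libraries.

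Gene groups were 25 gene lists and 16 lists of cell type markers, fixed before the data were examined. The 39 lists with at least 3 genes tested went through camera with a preset inter-gene correlation of 0.01, adjusted over the 39 lists. Of these, 10 were called higher and 8 lower. With the correlation estimated per list 0 were called (smallest adjusted p = 0.246), and fry called 1. A count "adjusted over the list alone" uses the limma p-values of that list's genes only. Counts over all genes are those of limma unless another tool is named. Some lists share genes, and the number shared is given where it matters. List levels per library are means of log2 values centred on the 5 libraries.

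Genes were named by a rule set before the data were examined: 13 fixed genes of the Hedgehog pathway and fibroblast subtypes; in each direction up to 8 genes by fold change among those past the threshold with a mean of at least 50 and non-overlapping groups, filled up by the smallest unadjusted p and said to be so; up to 4 members per described list by smallest p; and up to 3 markers of highest mean per other cell type. Other genes spelled out beside a count were chosen after their values were seen. Some genes of the rule and the lists are not reported here. Coordinates are those of GENCODE M21 (GRCm38), taken for the 14755 genes whose versioned identifier was the same.

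Alternatives were the pseudocount, the filter on low values, rescaling by total, upper quartile or quantiles, limma without trend, with robust variances or with array weights, a replicate block, leaving out each library, and for lists the estimated correlation and fry. Added after seeing the data were edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, edgeR with the authors' size factors, reads thinned to the smallest library, and vehicle 2 and 3 against LDE225 2 alone. DESeq2 gave no adjusted p for 257 genes. Differences between groups of fewer than 4 samples were not screened for outlying samples.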

Results

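Fibroblasts sorted from mouse pancreatic tumours were profiled by RNA sequencing after treatment of the mice with vehicle or with LDE225 (sonidegib), an inhibitor of Smoothened, the membrane protein that passes on the Hedgehog signal. The tumours were KPC tumours, a mouse model of pancreatic cancer. LDE225 or vehicle was given by oral gavage for 14 days once tumours had formed. The sorted cells were alive by DAPI exclusion, carried the fibroblast surface protein podoplanin (PDPN), and lacked CD45 (leukocytes), EpCAM and E-cadherin (epithelial cells). There were 3 vehicle libraries and 2 LDE225 libraries, measured as DESeq2-normalised counts of 15180 protein-coding genes.

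The reads recovered per library from the normalised values came to 7578822, 11194991 and 9319936 for vehicle replicates 1, 2 and 3, and to 13671817 and 14083280.0 for LDE225 replicates 1 and 2. Both LDE225 libraries thus held more reads on the deposited genes than every vehicle library. At this depth 1 read was worth between 0.803 and 1.27 normalised units. Pearson correlations of log2 values across genes, which are not independent replicates, ranged from 0.910 (vehicle 1 with vehicle 2) to 0.959 (LDE225 1 with LDE225 2). The first principal component held 38.9% of the variance and placed the LDE225 libraries at 39.1 and 41.1, vehicle 1 at -8.32, vehicle 3 at -6.69 and vehicle 2 at -65.2. The second component, with 33.1%, set vehicle 1 (70.7) apart from the other libraries (-24.6 to -5.90).

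The comparison of LDE225 with vehicle asks how blocking Hedgehog signalling alters tumour fibroblasts and the balance of their subtypes. Gli1, a transcription factor induced by Hedgehog signalling and a standard readout of the pathway, fell 17.8-fold, from 348 ± 104 normalised counts (SD, n = 3) with vehicle to 18.4 ± 5.75 (SD, n = 2) with LDE225 (log2 fold change -4.16 ± 0.34, SE, adjusted p = 0.0355). Its values were 315, 463 and 264 in the vehicle libraries and 22.5 and 14.4 in the LDE225 libraries. Ptch1, which encodes the Hedgehog receptor and is itself a target, had 688 ± 341 with vehicle and 193 ± 19.7 with LDE225 (log2 fold change -1.72 ± 0.36, adjusted p = 0.159). Ptch1 did not pass the test over all genes, although both LDE225 libraries lay below every vehicle library. Hhip, another target, was at 14.0 in vehicle 3 and at 0 in the other 4 libraries, and was not tested.

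**Figure D1:**
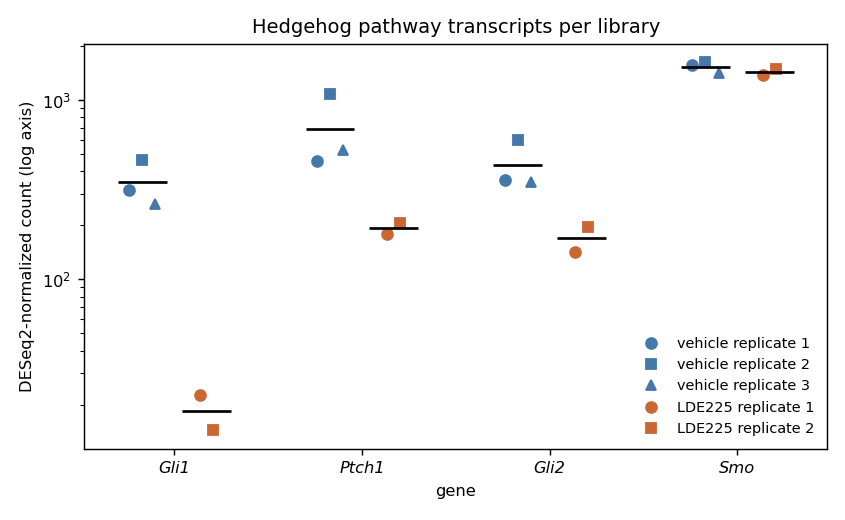
DESeq2-normalised counts (log axis) of 4 Hedgehog pathway genes in each library, with vehicle in blue, LDE225 in orange and a black line at each group mean. Gli1 was between 264 and 463 in the vehicle libraries and at 22.5 and 14.4 in the LDE225 libraries, while Smo lay between 1374 and 1619 in the 5 libraries.

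Gli1 (ENSMUSG00000025407.7) lies on chromosome 10 from 127329882 to 127341974 on the minus strand of GRCm38, where it overlaps Arhgap9 on the opposite strand. Among 16 measured Hedgehog target genes, 1 passed the test adjusted over all genes (Gli1, lower) and 6 passed when adjusted over the list alone. Of these 3 fell, Gli1 and Ptch1 among them, and 3 rose: the cell cycle inhibitor Cdkn1c (log2 fold change 2.15), the growth factor Igf1 (0.97) and the secreted Wnt antagonist Sfrp1 (1.07). The target list, which shares Sfrp1 and Wnt5a with the list of Wnt genes, was not called as a group (median log2 fold change -0.35, camera adjusted p = 0.399). Its median was -0.070 without vehicle 3 and -0.094 without LDE225 1. None of 19 Hedgehog pathway components passed either adjustment (list median 0.068, mean -0.0064, camera adjusted p = 0.690). Their median was -0.019 without LDE225 2. Smo, which encodes the target of the drug, had 1535 ± 104 and 1434 ± 85.9 (adjusted p = 0.833), and the transcription factor Gli2 had 436 ± 142 and 169 ± 38.1 (log2 fold change -1.33 ± 0.29, adjusted p = 0.168). The log2 fold change of Gli1 lay between -4.46 and -3.85 without vehicle 1, vehicle 3, LDE225 1 or LDE225 2, and each of these omissions ended its call (limma adjusted p between 0.0580 and 0.529). The call was also absent in edgeR's quasi-likelihood test on the recovered reads (-4.22, adjusted p = 0.0552). DESeq2 on the same reads called Gli1 and Ptch1 (adjusted p = 0.000914 for Ptch1).

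Across 13183 genes tested, 3 rose and 1 fell with LDE225. Ace, which encodes angiotensin-converting enzyme, rose 6.16-fold, from 1689 ± 291 (SD, n = 3) to 10304 ± 339.5 (SD, n = 2; log2 fold change 2.62 ± 0.19, SE, adjusted p = 0.0355). Mmp11, which encodes a stromal metalloproteinase, rose 5.57-fold, from 242 ± 43.5 to 1341 ± 154 (log2 fold change 2.48 ± 0.19, adjusted p = 0.0355). Col28a1, a collagen gene, rose 6.19-fold, from 271 ± 67.3 to 1647 ± 17.7 (log2 fold change 2.63 ± 0.23, adjusted p = 0.0376). Gli1 was the gene that fell. Ace (ENSMUSG00000020681.14) lies on chromosome 11 from 105967945 to 105989964 (plus strand), Mmp11 (ENSMUSG00000000901.17) on chromosome 10 from 75923222 to 75936496 (minus strand, overlapping Chchd10 on the other strand) and Col28a1 (ENSMUSG00000068794.7) on chromosome 6 from 7997808 to 8192617 (minus strand), all in GRCm38.

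The genes with the next smallest unadjusted p did not pass the adjusted test of limma. Those named below were not called by edgeR either, while DESeq2 on the recovered reads called each of them. Above vehicle in both LDE225 libraries were Pla1a, a phospholipase gene (803 ± 204 with vehicle and 4237 ± 229 with LDE225, log2 fold change 2.43 ± 0.24, adjusted p = 0.0664), Islr (1.53), the thrombospondin gene Thbs4 (2.01), Igsf10 (1.59) and the cathepsin gene Ctsf (1.42), these 4 each at adjusted p = 0.0731. Islr overlaps its neighbour Islr2 on the same strand, so that reads may be divided between them. Below vehicle in both were the apolipoprotein gene Apob (413 ± 210.1 and 16.3 ± 7.57, log2 fold change -4.54 ± 0.46, adjusted p = 0.0731), P-cadherin (Cdh3, -1.86), the proliferation marker Mki67 (-1.41) and the endosomal adaptor gene Rab11fip1 (-1.41), all at the same adjusted p. The mitotic cyclins Ccnb2 (-1.53) and Ccna2 (-1.54) and histidine decarboxylase (Hdc, -1.32) followed, with adjusted p between 0.0747 and 0.0819.

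**Figure D2:**
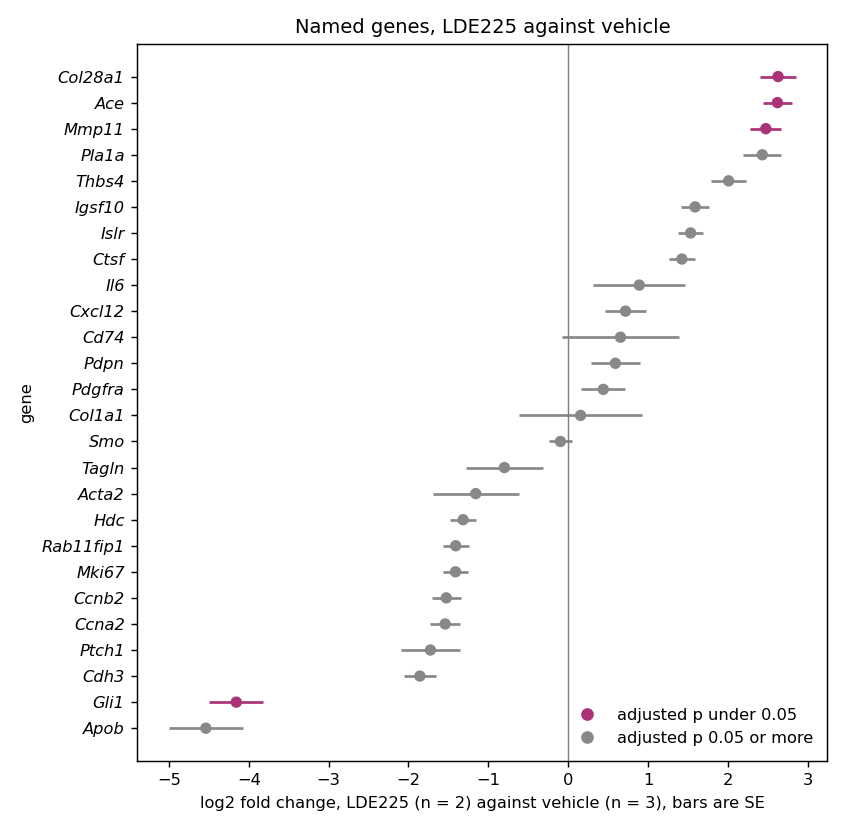
Log2 fold change of LDE225 (n = 2) against vehicle (n = 3) for the named genes, with bars of 1 SE, and with genes under an adjusted p of 0.05 in purple. Ace, Mmp11 and Col28a1 lie between 2.48 and 2.63, Gli1 lies at -4.16, and the log2 fold change of Col1a1 (0.16) turned under quantile normalisation (-0.065).

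At an unadjusted p under 0.05 there were 1665 genes (912 higher, 753 lower), where 659 would pass by chance. The groups did not overlap for 16.6% of genes with LDE225 higher and 15.2% with LDE225 lower, where chance gives 10% each. Leaving out 1 library moved the counts of called genes to 0 higher and 0 lower (without vehicle 1, or without LDE225 1), 6 and 1 (without vehicle 2), 1 and 0 (without vehicle 3) or 0 and 4 (without LDE225 2). Without vehicle 1, vehicle 3, LDE225 1 or LDE225 2 the log2 fold change of Ace lay between 2.59 and 2.74, the log2 fold change of Mmp11 between 2.36 and 2.62 and the log2 fold change of Col28a1 between 2.62 and 2.81, and none of the 3 was called. On recovered reads, edgeR called 2 higher (Ace and Mmp11) and 0 lower, and DESeq2 called 300 higher and 230 lower, among them all 4 genes called by limma.

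Cancer-associated fibroblasts (CAFs) of the pancreas are grouped into inflammatory, myofibroblastic and antigen-presenting types. Inflammatory CAF genes were higher with LDE225 as a group (camera adjusted p = 6.05e-08, and adjusted p = 0.883 with an estimated correlation). Of these genes, 28 of 34 had positive log2 fold changes, with a median of 1.08. The groups were separated for 19 of them, where chance gives 10% and 16.6% of all genes tested were separated that way. In limma 0 passed when adjusted over all genes, while 18 passed at an unadjusted p under 0.05, edgeR called 0 and DESeq2 11. Adjusted over the list alone 10 rose and 0 fell. Svep1, which encodes an extracellular adhesion protein, had 7187 ± 2865 (SD, n = 3) with vehicle and 38755 ± 32.6 (SD, n = 2) with LDE225 (log2 fold change 2.51 ± 0.34, SE), and the dipeptidase gene Dpep1 had 524 ± 165 and 2028 ± 233 (1.99 ± 0.26). Plpp3 (1.71) and Ccn3 (0.97) also rose over the list alone. The 6 others were Adamts5, Ogn, Efemp1, Fbln1, Col14a1 and Gsn, named after their values were seen. None of these genes that rose over the list alone is a chemokine. The list shares 7 genes with the list of chemokines, which was not called (median -0.091, camera adjusted p = 0.930). Of the signalling molecules in the list, Il6 had 1608 ± 1266 and 2551 ± 935 (adjusted p = 0.587), the chemokine Cxcl12 2691 ± 636 and 4434 ± 1182 (adjusted p = 0.317), and the receptor Pdgfra a log2 fold change of 0.44 ± 0.27 (adjusted p = 0.573). With 1 library left out, the log2 fold change of Il6 was 0.51 (without vehicle 1), 1.49 (vehicle 3) or 0.51 (LDE225 2), the log2 fold change of Cxcl12 0.44 (LDE225 1) and the log2 fold change of Pdgfra 0.67 (vehicle 1) or 0.28 (vehicle 3), and the latter was 0.22 with quantile normalisation. The mean level of the list, relative to the 5 libraries, was -0.73, -1.13 and 0.34 in the vehicle libraries and 0.68 and 0.83 in the LDE225 libraries.

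Myofibroblastic CAF genes were not called as a group: 19 of 30 had negative log2 fold changes, with a median of -0.32 (camera adjusted p = 0.121). The list was called lower without vehicle 1 (median -0.60, adjusted p = 0.00124), without LDE225 2 (-0.43, adjusted p = 0.0209) and with array weights (-0.43, adjusted p = 0.0351). Its median was -0.15 (adjusted p = 0.692) without vehicle 2. Only Mmp11 passed over all genes, and 4 passed when adjusted over the list alone, of which Mmp11 and the growth factor binding protein gene Igfbp3 (log2 fold change 1.80) rose and Tpm2 (-0.96, tropomyosin) and Des (-0.83, desmin) fell. Des and Cnn1 are also among the pericyte and smooth muscle markers, which were lower (median -0.71, camera adjusted p = 0.0320; adjusted p = 0.883 with an estimated correlation). Acta2, smooth muscle actin, was at 1991, 6821 and 6728 in the vehicle libraries and at 1762 and 2314 in the LDE225 libraries (log2 fold change -1.16 ± 0.54, SE, adjusted p = 0.444), and Tagln, transgelin, had 3696 ± 1813 and 1915 ± 341 (-0.80 ± 0.48, adjusted p = 0.561). Vehicle 1 was thus as low in Acta2 as the LDE225 libraries, and without it the log2 fold change of Acta2 was -1.75 and the log2 fold change of Tagln -1.32. Antigen-presenting CAF genes were not called (median 0.081 with a camera direction of lower, adjusted p = 0.781). Their median turned to -0.14 without vehicle 2 and -0.14 without LDE225 1. It was 0.44 without vehicle 1, 0.14 without vehicle 3 and 0.32 without LDE225 2. It also turned at a mean of at least 50 (-0.15) and with the same total (-0.052). Over that list alone Scara3 (1.88) rose, and Ezr (-0.89, ezrin) and Slpi (-1.39, a protease inhibitor) fell. Cd74, the invariant chain of major histocompatibility complex class II, had 860.2 ± 676 and 1238 ± 855 (log2 fold change 0.66 ± 0.73, adjusted p = 0.769), and the log2 fold change of Cd74 turned without LDE225 1 (-0.11). It was 1.27 without vehicle 1, 0.049 without vehicle 2 and 1.43 without LDE225 2.

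Universal fibroblast genes, which mark progenitor-like fibroblasts of many organs, were higher in 16 of 18 cases (median 1.24, camera adjusted p = 6.41e-05; adjusted p = 0.883 with an estimated correlation), although in limma 0 passed over all genes or over the list alone, while 7 passed at an unadjusted p under 0.05, edgeR called 0 and DESeq2 2. The peptidase gene Dpp4 had 314 ± 252 (SD, n = 3) and 1329 ± 8.09 (SD, n = 2), and the extracellular matrix gene Tnxb had 6561 ± 5049.6 and 34400.5 ± 4078, so that the vehicle libraries varied widely. The median was 0.66 without vehicle 2 and 0.66 without LDE225 2. This list shares 4 genes (Dpt, Has1, Ly6c1 and Pi16) with the inflammatory list. Pan-fibroblast markers were also higher (12 of 15, median 0.40, camera adjusted p = 0.0472; adjusted p = 0.883 with an estimated correlation), with Mmp2, Lum and Fbln1 rising over the list alone and 0 over all genes. That call was lost without vehicle 1 (median 0.027), LDE225 1 (0.43) or LDE225 2 (0.36). It was also lost with quantile normalisation (0.19, adjusted p = 0.268), array weights (0.21, adjusted p = 0.115) or no filter on low values (0.40, adjusted p = 0.0568). Col1a1, the main fibrillar collagen gene, had 359251 ± 137500.0 and 376432 ± 2023 (log2 fold change 0.16 ± 0.77, adjusted p = 0.958), and Pdpn, the protein used for sorting, had 3403 ± 1108 and 4924 ± 366 (adjusted p = 0.492). The log2 fold change of Col1a1 turned without vehicle 1 (-0.22) and was 0.34 without vehicle 2 and 0.35 without vehicle 3, and the log2 fold change of Pdpn (0.59) was 0.28 without vehicle 2.

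**Figure D3:**
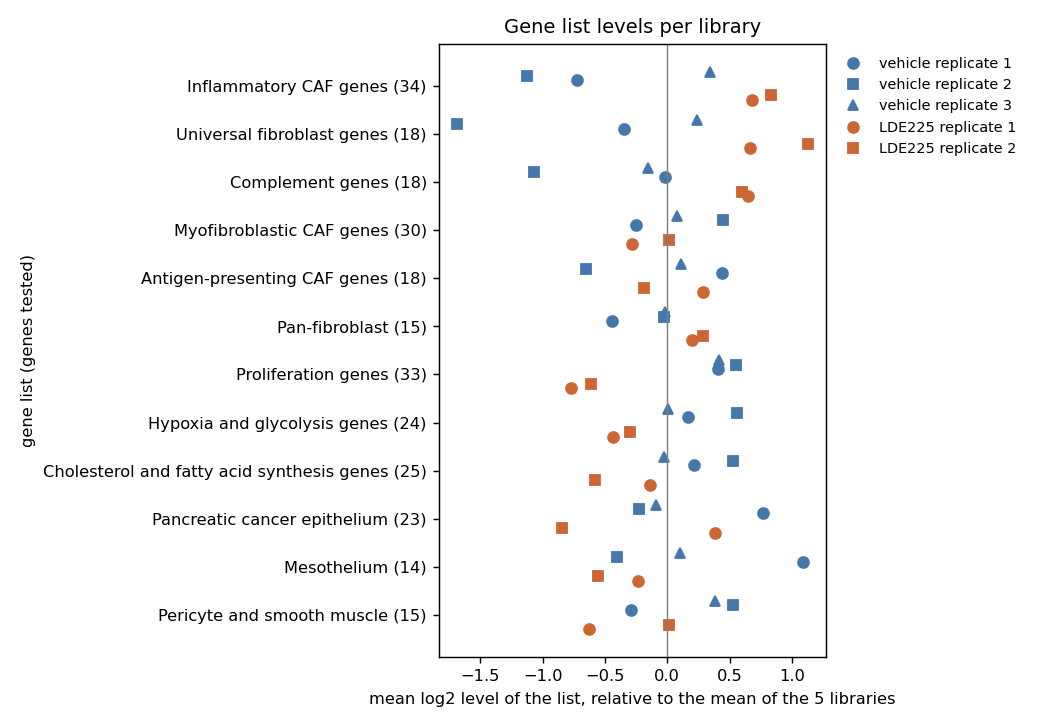
Mean log2 level of 12 gene lists in each library relative to the mean of the 5 libraries, with vehicle in blue, LDE225 in orange, and the number of genes tested in brackets. Proliferation genes lay at 0.41, 0.55 and 0.42 in the vehicle libraries and at -0.77 and -0.61 in the LDE225 libraries, while the epithelial markers overlapped between the groups.

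Proliferation genes were lower with LDE225 in 33 of 33 cases, with a median log2 fold change of -1.29 (camera adjusted p = 2.47e-27, and adjusted p = 0.246 with an estimated correlation). The groups were separated for 31, where chance gives 10% and 15.2% of all genes tested were separated that way. Adjusted over the list alone 30 fell. Over all genes limma called 0, while 31 passed at an unadjusted p under 0.05, edgeR called 0 and DESeq2 21. Mki67 had 1323 ± 141 (SD, n = 3) and 497 ± 56.8 (SD, n = 2), Ccnb2 287 ± 5.95 and 98.9 ± 4.72, Ccna2 299.7 ± 24.3 and 102 ± 7.17, and the mitotic kinesin gene Kif20a 445 ± 37.9 and 173 ± 40.0. The list median stayed between -1.33 and -1.14 when any 1 library was left out, and the list was the only one called by fry (adjusted p = 0.0193). The markers of pancreatic cancer epithelium had a median of -0.72 (camera adjusted p = 0.00178; adjusted p = 0.883 with an estimated correlation), which was -1.16 without LDE225 1, with the call lost without vehicle 1 (-0.56) or LDE225 2 (-0.15). Their level was 0.38 in LDE225 1, above vehicle 2 (-0.22) and vehicle 3 (-0.09).

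Genes of glycolysis and hypoxia were lower in 20 of 24 cases (median -0.85, camera adjusted p = 7.81e-07; adjusted p = 0.883 with an estimated correlation). Adjusted over the list alone 14 fell and 1 rose. Over all genes limma called 0, while 19 passed at an unadjusted p under 0.05, edgeR called 0 and DESeq2 12. Pgk1, a glycolytic kinase gene, had 3877 ± 1118 (SD, n = 3) and 1612 ± 246 (SD, n = 2), the lactate transporter gene Slc16a3 1325 ± 407 and 547 ± 134, and the oxygen sensor gene Egln3 1038 ± 220.1 and 425 ± 93.9. The gene that rose was Adm, which encodes the vasodilator peptide adrenomedullin (187 ± 42.9 and 583 ± 55.9). Genes of cholesterol and fatty acid synthesis were lower in 24 of 25 cases (median -0.62, camera adjusted p = 7.81e-07; adjusted p = 0.883 with an estimated correlation). Adjusted over the list alone 4 fell, among them Cyp51 (-0.62), Fdps (-1.12) and Sqle (-1.13), all enzymes of sterol synthesis. Over all genes limma called 0, while 10 passed at an unadjusted p under 0.05, edgeR called 0 and DESeq2 4. The median of this list was -0.31 without LDE225 2 and -0.84 without LDE225 1, where that of the epithelial markers (-0.72, camera adjusted p = 0.00178; adjusted p = 0.883 with an estimated correlation) was -0.15 and -1.16. Levels in LDE225 1 and 2 were -0.14 and -0.58 for the list and 0.38 and -0.85 for those markers.

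Complement genes were higher in 17 of 18 cases (median 0.96, camera adjusted p = 3.47e-06; adjusted p = 0.883 with an estimated correlation). Serping1, which encodes the C1 inhibitor (9347 ± 2111, SD, n = 3, and 25616 ± 2021, SD, n = 2), C2 (1.67 on the log2 scale) and C4b (2.83) were among 4 that rose over the list alone. Over all genes limma called 0, while 8 passed at an unadjusted p under 0.05, edgeR called 0 and DESeq2 5. C4b has a near-identical copy in the mouse genome, so its value is uncertain. Matrix proteases and their inhibitors had a median of 0.26 (camera adjusted p = 0.0312; adjusted p = 0.883 with an estimated correlation), with 7 rising and 1 falling over the list alone and 0 over all genes. Mmp2 had 11845 ± 2144 and 32459 ± 3461, the cathepsin gene Ctsk 1402 ± 323 and 3672 ± 876, Ctsl 7165 ± 1248 and 13380.3 ± 646, and Mmp3 942 ± 559.5 and 3362 ± 168. The member that fell was Plaur, the urokinase receptor gene, named after its value was seen. Other matrix proteins and crosslinking enzymes had a median of 0.20 (camera adjusted p = 0.0357; adjusted p = 0.883 with an estimated correlation) and 0 genes past either adjustment. The protease median was 0.40 without vehicle 2 and 0.39 without LDE225 1, and that of the other matrix proteins 0.36 without vehicle 3 and 0.37 without LDE225 1. Both calls were lost without vehicle 1 (medians 0.12 and 0.049) or without LDE225 2 (0.088 and 0.14). They were also lost with quantile normalisation (0.072 and 0.094, adjusted p = 0.101 and 0.484) or array weights (0.12 and 0.044, adjusted p = 0.104 and 0.335). Fibrillar and basement membrane collagens were not called (13 of 18 negative, median -0.24, camera adjusted p = 0.193). They were called lower without vehicle 1 (-0.51, adjusted p = 0.00328) and with quantile normalisation (-0.33, adjusted p = 0.0336). Their median was -0.0076 without vehicle 2 and -0.15 without vehicle 3.

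Among signalling lists, Wnt pathway genes had a median of 0.54 with 22 of 30 positive (camera adjusted p = 0.00961; adjusted p = 0.883 with an estimated correlation), and the secreted antagonists Sfrp4 and Sfrp2 had 401 ± 367 and 1637 ± 1126 (SD, n = 3) with vehicle against 2683 ± 170.3 and 8347 ± 441 (SD, n = 2) with LDE225. The median was 0.91 without LDE225 1, and the call was lost without LDE225 2 (median 0.29). Unfolded protein response genes had a median of 0.27 with 17 of 21 positive (camera adjusted p = 0.00785; adjusted p = 0.883 with an estimated correlation). It was 0.54 without LDE225 2, and the call was lost without vehicle 2 (0.24) or LDE225 1 (0.14) and with quantile normalisation (0.16). Immediate-early genes had a median of 0.37 with 20 of 24 positive (camera adjusted p = 0.0298; adjusted p = 0.883 with an estimated correlation). It was 0.56 without vehicle 3 and 0.59 without LDE225 1, and the call was lost without vehicle 2 (0.13) or LDE225 2 (0.16) and with quantile normalisation (0.21) or array weights (0.33). Interferon response genes had a median of -0.26 with 25 of 35 negative (camera adjusted p = 0.00961; adjusted p = 0.883 with an estimated correlation). It was -0.43 without vehicle 2, and the call was lost without vehicle 1 (-0.057) or LDE225 1 (-0.24) and with array weights (-0.17). In a comparison of vehicle 2 and 3 with LDE225 2 alone, chosen after seeing the data, the interferon median turned to 0.037 (adjusted p = 0.829), and the cause was not tested. In these 4 lists 0 genes passed over all genes or over the list alone. TGF-beta response genes (median 0.20, camera adjusted p = 0.114) and BMP and growth factor genes (0.40, adjusted p = 0.121) were not called, though over each list alone 1 gene rose, the receptor gene Tgfbr2 (6611 ± 1369 and 16611 ± 2017) and the growth factor gene Fgf7 (112 ± 17.7 and 375 ± 81.5). The TGF-beta list was called higher without vehicle 3 (0.32, adjusted p = 0.0166) or LDE225 1 (0.33, adjusted p = 0.0106). Its median was 0.088 without vehicle 2 and 0.079 (adjusted p = 0.767) without LDE225 2. The BMP list was called higher without vehicle 3 (0.56, adjusted p = 0.00473), at a mean of at least 50 (0.49, adjusted p = 0.0385) and with the same total (0.27, adjusted p = 0.0221). Its median was 0.14 without vehicle 1 and 0.25 without vehicle 2. Chemokines (median -0.091, mean 0.030, adjusted p = 0.930), NF-kB and cytokine response genes (0.18, adjusted p = 0.632), p53 targets (-0.035, mean 0.027, adjusted p = 0.930) and heat shock genes (-0.017, mean 0.058, adjusted p = 0.949) were not called and held 0 genes past either adjustment. All 4 medians changed sign when 1 library was left out: chemokines without vehicle 3 (0.035), LDE225 1 (0.052) or vehicle 1 (0.00010), NF-kB genes without vehicle 2 (-0.10), p53 targets without vehicle 3 (0.019), and heat shock genes without vehicle 1 (0.012), vehicle 3 (0.024) or LDE225 2 (0.11).

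Markers of other cell types were measured because a sort can carry them over. Epithelial markers were lower in 16 of 23 cases (median -0.72, camera adjusted p = 0.00178; adjusted p = 0.883 with an estimated correlation), and Tff1, Lgals4, Krt20, Krt8, Krt19 and Sox9 fell over the list alone, with 0 over all genes. Krt8 had 1833 ± 241 (SD, n = 3) and 895 ± 404 (SD, n = 2), and Krt18 1225 ± 60.8 and 755 ± 543. Krt19 is shared with the mesothelial markers. The median was -1.16 without LDE225 1, and the call was lost without vehicle 1 (-0.56) or LDE225 2 (-0.15). Mesothelial markers were lower in 13 of 14 cases (median -0.77, camera adjusted p = 0.0165; adjusted p = 0.883 with an estimated correlation), with Krt19, Upk1b and Msln falling over the list alone, and the call was lost without vehicle 1 (-0.24) or LDE225 2 (-0.54) and with the same total (-0.90, adjusted p = 0.0951). Pericyte and smooth muscle markers had a median of -0.71 with 11 of 15 negative (camera adjusted p = 0.0320; adjusted p = 0.883 with an estimated correlation), a call lost without vehicle 2 (-0.63), vehicle 3 (-0.60) or LDE225 1 (-0.47) and with quantile normalisation (-0.69), the same total (-0.83) or a mean of at least 50 (-0.73). Macrophage markers were not called (median 0.056, adjusted p = 0.632), although 2 rose over the list alone, Apoe among them, and Lyz2 was at 353 ± 180.1 and 443 ± 202. Neutrophil markers were not called (-0.16, mean 0.045, adjusted p = 0.690), though Hdc fell over the list alone. Blood endothelium (-0.0095 with a camera direction of higher, adjusted p = 0.999), lymphatic endothelium (0.85, adjusted p = 0.408), dendritic cells (-0.29, adjusted p = 0.435), erythrocytes (-0.96, adjusted p = 0.142), Schwann cells and glia (-0.16, mean 0.14, adjusted p = 0.930), adipocytes (0.049, adjusted p = 0.937) and acinar cells (0.35, adjusted p = 0.930) were not called. Without vehicle 3 the erythrocyte markers were called lower (-2.25, adjusted p = 0.00407) and the lymphatic markers higher (1.45, adjusted p = 0.00986). Without vehicle 2 the erythrocyte median was -0.56 and the lymphatic median turned to -0.062. Without LDE225 2 they were -2.58 and 0.48. Other medians that changed sign were those of macrophages without vehicle 2 (-0.25) or LDE225 2 (-0.10), neutrophils without vehicle 1 (1.23) or LDE225 2 (0.26), dendritic cells without LDE225 1 (0.19) and Schwann cells without vehicle 1 (0.29). So did those of blood endothelium without vehicle 1 (0.20), vehicle 3 (0.38) or LDE225 1 (0.62), adipocytes without vehicle 1 (-0.17), vehicle 3 (-0.27) or LDE225 2 (-0.035), and acinar cells without vehicle 2 (-1.11) or LDE225 2 (-1.30). Between vehicle 2 and 3 and LDE225 2 alone, the comparison chosen after seeing the data, the acinar markers were called higher (adjusted p = 0.00214). T and NK cells and B and plasma cells had too few measured members for a test.

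Libraries also differed in single marker groups. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were at 0 in LDE225 1, where 3 reads would be 2.41 normalised units, and between 217 and 1068 in the other 4 libraries (camera adjusted p = 0.0472; adjusted p = 0.883 with an estimated correlation). Without LDE225 1 that list had a median of 0.026 and without LDE225 2 one of -8.27, and the call was lost without LDE225 1 or any 1 vehicle library (adjusted p between 0.0850 and 0.780) and with the same total, upper-quartile scaling, quantile normalisation or array weights (adjusted p between 0.0626 and 0.144). The islet hormone genes Ins1, Ins2 and Iapp were at 111, 110.1 and 71.5 in LDE225 1, Ins2 was at 2.54 in LDE225 2, and all others were listed at 0 (camera adjusted p = 0.0472; adjusted p = 0.883 with an estimated correlation), a call lost without LDE225 1 or any 1 vehicle library (adjusted p between 0.0898 and 0.212), with quantile normalisation, array weights or a pseudocount of 8 (adjusted p between 0.0675 and 0.104), and kept without LDE225 2 (adjusted p = 1.98e-12). Mitochondrially encoded genes were not called (median 0.058, adjusted p = 0.408), with medians of -0.084 without vehicle 2 and -0.13 without LDE225 1, while mt-Nd4l was at 0 in every vehicle library and at 61.1 and 49.9 in the LDE225 libraries and rose over the list alone. It overlaps mt-Nd4 (1827 to 2882 in the 5 libraries), with which reads can be shared, so its value is uncertain.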

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

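The edgeR, DESeq2 and thinned-read settings and the reduced set of libraries were chosen after seeing the data. The counts of genes called (3 higher and 1 lower) stayed within 1.5 times under both other pseudocounts, both other filters, upper-quartile and quantile scaling and robust variances. Rescaling to the same total gave 2 lower genes and shifted the median of all genes by -0.13. No trend gave 2 higher and 0 lower, with 0 of the 4 called genes among them (adjusted p = 0.169 for Ace, 0.186 for Mmp11 and 0.225 for Col28a1). Array weights gave 70 higher and 38 lower, and the cause was not tested for these. DESeq2 on recovered reads gave 300 higher and 230 lower, and edgeR gave 0 lower with its own or with the authors' size factors. On simulated counts DESeq2 called 52 unchanged genes and limma 11, which leaves most of the gap in calls unexplained. Vehicle 2 and 3 against LDE225 2 alone gave 0 higher and 0 lower, with fewer samples. Leaving out 1 library gave 0 to 6 higher and 0 to 4 lower, where a group left with 1 library is assumed to vary like the other. With the replicate number as a block, 16 were higher and 5 lower, the 4 called genes among them. The deviations of same-numbered libraries correlated at 0.13 and -0.017 over only 2 shared numbers. With 2 LDE225 libraries the deviations of that group mirror each other, so these correlations say little about pairing. The labels do not say what the numbers mean, so the numbers are not taken to pair the samples. The block also called the BMP (0.56), TGF-beta (0.32), lymphatic (1.45) and mitochondrial (0.18) lists higher and the erythrocyte list (-2.25) lower. It no longer called the islet list. Replicate number 3 occurs only among the vehicle libraries, so vehicle 3 adds nothing to the group difference in that fit. Each of these medians equals the one without vehicle 3. For these medians the block is thus not a check separate from that omission. Its counts of called genes (16 and 5) did differ from those without vehicle 3 (1 and 0).

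The log2 fold change of Gli1 kept its direction but lost its call without trend (-4.16, adjusted p = 0.169), in edgeR (-4.22, adjusted p = 0.0552), in edgeR with the authors' size factors (-4.23, adjusted p = 0.0563) and in the reduced set (-4.51, adjusted p = 0.463). It ranged from -4.46 to -3.85 with 1 library left out. The log2 fold change of Ptch1 (-1.83) passed only in DESeq2. Lists higher numbered 10 at first, 4 with quantile scaling, 5 with array weights, 6 in the reduced set, 0 with estimated correlation, 0 with fry and 5 to 12 with 1 library left out. Lists lower numbered 8 at first, 5 with the same total, 4 in the reduced set, 0 with estimated correlation, 1 with fry and 5 to 7 with 1 library left out. The reduced set lost the pan-fibroblast (0.15), protease (0.21), other matrix (0.11), unfolded protein (0.17), mesothelial (-0.37), pericyte and islet lists, and reads thinned to the smallest library lost the islet and sex-linked lists. Medians of lists not called turned with the same total for Hedgehog components (-0.065), antigen-presenting (-0.052), mitochondrial (-0.076), adipocyte (-0.085) and macrophage (-0.076) genes. They turned at a mean of at least 50 for antigen-presenting (-0.15), macrophage (-0.10) and neutrophil (0.87) genes and with quantile scaling for mitochondrial (-0.059) and adipocyte (-0.038) genes. They also turned with array weights for mitochondrial (-0.037), neutrophil (0.55) and Schwann cell (0.13) genes, with no filter for adipocyte genes (-0.11) and with thinned reads for macrophage genes (-0.022). The reduced set turned those of mitochondrial (-0.12), adipocyte (-0.22), blood endothelium (0.82), dendritic cell (0.0025), neutrophil (0.51) and Schwann cell (0.028) genes. With the same total, calls were kept at medians of 0.26 (pan-fibroblast), 0.12 (protease), 0.064 (other matrix), 0.14 (unfolded protein), 0.24 (immediate-early) and -0.39 (interferon). The cause was not tested for these. The log2 fold change of Col1a1 (0.16) turned with quantile scaling (-0.065), array weights (-0.072), without vehicle 1 (-0.22) and in the reduced set (-0.22), and the cause was not tested; it ranged from -0.22 to 0.35 with 1 library left out. The log2 fold change of Cd74 turned without LDE225 1 (-0.11), with a range of -0.11 to 1.43. The sex-linked list turned without LDE225 1 (0.026) and in the reduced set (0.060), both of which lack that library, with a range of -8.27 to 0.026. The interferon list turned in the reduced set (0.037), the cause was not tested, and it ranged from -0.43 to -0.057 with 1 library left out.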

Other observations

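Tests of depth, carcinoma cells, vehicle 2 and the share of fibroblasts, and their repeats with 1 library left out, were chosen after the results were seen, as were the lysosomal and histone lists, whose bounds for members not yet looked at, like those for the X-linked genes, were written before those values were seen. Genes of lysosomal enzymes and membrane proteins stood among the genes with small p that were higher with LDE225, and a list of 53 was tested. Its 46 members whose values had not been looked at had a median log2 fold change of 0.40, with 41 positive (camera p = 7.87e-10, unadjusted; p = 0.0659 with an estimated correlation). Of members picked after their values were seen, Psap, a sphingolipid activator, was at 11936, 11272 and 10933 in the vehicle libraries and at 17330.3 and 20953 in the LDE225 libraries, and the protease gene Ctsd was at 4484, 4146 and 4688 against 6078 and 7048. Ctss, counted among the 46, is also a macrophage marker whose list had already been tested. The hypothesis of a broad rise of lysosomal transcripts met its bound, but the estimated correlation leaves it open.

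Replication-dependent histone genes, whose transcripts lack a poly(A) tail and are kept by ribosomal depletion, stood among those lower. The 49 members not looked at before had a median of -1.04, with 46 negative (camera p = 2.72e-17, unadjusted; p = 0.0945 with an estimated correlation). H1f3, picked after its values were seen, was at 264, 579 and 256 in the vehicle libraries and at 117 and 171 in the LDE225 libraries. Histone genes are near-identical in sequence, so values of single members are uncertain.

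The mean level of the inflammatory list minus that of the myofibroblastic list, a measure chosen after the data were seen, was -0.47, -1.57 and 0.26 in the vehicle libraries and 0.96 and 0.82 in the LDE225 libraries. The difference of 1.49 has an exact permutation p = 0.2 (two-sided) over 10 arrangements. Vehicle 1 with vehicle 2 against the other libraries gave a larger absolute difference, so the treatment split was not the most extreme.

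The proliferation list was lower in both LDE225 libraries. Those libraries held more recovered reads on the deposited genes, and the median was -1.23 after thinning all reads to the smallest library. The values were already scaled for depth, and thinning hardly moves fold changes of genes with many reads. With read numbers made equal the list was still lower, which argues against read number alone as the source of the fall. Other differences that may go with read number were not tested. A lower carry-over of epithelial carcinoma cells, which the EpCAM and E-cadherin gate should remove, would lower their markers as much, and their median was -0.72 (95% bootstrap interval over markers -0.86 to -0.38) against -1.29 for proliferation. That gap rests on LDE225 1: without it the medians were -1.16 (interval -1.38 to -0.88) and -1.14, and without LDE225 2 they were -0.15 and -1.25, so carry-over stays open. Slower cycling of fibroblasts under LDE225 is another candidate explanation, as are carcinoma cells without EpCAM and E-cadherin and untested differences between tumours.

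The inflammatory list was higher in both LDE225 libraries. Vehicle 2 had the lowest level, but without it the median was still 0.88, so that library alone does not account for the shift. Vehicle 1 was also low (-0.73), while vehicle 3 (0.34) lay nearer to the LDE225 libraries (0.68 and 0.83). A low level in vehicle 1 and vehicle 2 together was not tested. A larger share of fibroblasts would raise all fibroblast genes alike, if only fibroblasts expressed them. The 13 pan-fibroblast markers outside the list had a median of 0.34 (95% bootstrap interval over markers 0.16 to 0.59) against 1.08. Of these markers, Fap, Postn and Thy1 are also myofibroblastic list genes, and Pdgfrb is also a pericyte marker. The interval measures spread over markers and not over libraries, so the share of fibroblasts stays open. With each library left out in turn the interval still lay under the median of the list, most closely without vehicle 2 (0.28 to 0.82 against 0.88). A shift between fibroblast states may underlie the pattern, as a hypothesis found and examined on the same 5 libraries, with differences between tumours untested.

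LDE225 1 held no reads of 4 Y-linked genes. If the library came from a female mouse, the X-linked partners Kdm5c, Kdm6a, Eif2s3x and Ddx3x, which escape X inactivation, would be highest there, and 4 of the 4 were. Kdm6a was at 614 in LDE225 1 and at most 338 in the other libraries. Sex of the animal is thus a likely difference between LDE225 1 and the rest, and the sex of the mice is not given in the labels. Without LDE225 1 the proliferation list kept a median of -1.14 and the inflammatory list one of 1.29.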
